A study of Mus musculus with 2 samples.

How the data were processed

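Total RNA from the left cerebral cortex of 2 male mice, described in the labels as separate animals and numbered as biological replicates 1 and 2, was sequenced in 1 library each. The labels give both animals the same donor identifier. They name a tissue RNA purification kit and a spike-in profile for stranded, ribosomal RNA-reduced libraries.

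For each library the deposited files are a gene table and a matching transcript table, quantified from a transcriptome alignment per the file headers and the accompanying listing, and a further transcript table quantified directly from the reads. They are called the alignment-based and the read-based tables here. Both used mm10 and GENCODE M21 per the deposited listing. The aligner and the quantification tools are not given in the sources used here. The alignment-based tables hold deposited expected counts (estimated reads per gene or transcript, not normalized), deposited TPM over all rows, and the percent of a gene's TPM on each transcript, per the file headers. The read-based tables hold deposited estimated counts and TPM. Coverage tracks and alignments named in the listing were not used here. The gene tables list 55536 genes, 26248 tRNA rows and 97 spike-in rows, of which 96 are ERCC RNAs. Gene names, types and 1-based coordinates came from the GENCODE M21 annotation, which covered all 55536 genes, and 141767 of 141767 read-based transcripts carried the symbol of the annotation.

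How the values were made could affect them. Deposited effective lengths were 99 nucleotides under the transcript length in the alignment-based table and a median of 344 and 340.1 under it in the read-based table, which weighs short RNAs differently. Expected counts split reads shared by near-identical or overlapping genes, so such genes are reported as uncertain. TPM is a share of all RNA, including abundant small RNAs. A gene symbol held by several gene models was taken from the model with the highest mean count in the list comparisons, and 233 gene identifiers share a symbol.

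The levels reported are deposited TPM, with the mean and SD of the 2 mice. A gene was called expressed at a TPM of at least 1 in both mice. List levels are medians of log2(TPM + 1). Ratios between 2 genes used the same scale and were set against the 95th percentile of the absolute difference between the mice in 20 bins of abundance. Expected counts were rounded to whole numbers for edgeR 4.0.16 in R 4.3.3, with filterByExpr, TMM scaling and an intercept-only design, which gave the biological coefficient of variation. Log2 ratios between the mice used TMM-scaled expected counts with a prior count of 0.5. Genes with a ratio over 1 in size were counted among protein-coding genes with a mean count of at least 100, and their counting intervals are exact binomial at 95%. A list was compared through the percentile of its median ratio among 10000 random lists of the same size matched on mean count in 20 bins, over 16474 genes with a mean count of at least 20. That percentile describes these 2 libraries and is no test between conditions. The total counts of 27988085 and 29915463 set the precision, and 3 counts is the limit that a count of 0 allows. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.

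The steps were tested on simulated data first. For the comparison of replicate 2 with replicate 1 over 11728 genes, 96% of 100 genes changed 2.83-fold and 100% of 100 genes changed 8-fold were recovered, with 0 unchanged genes called. A coefficient of variation of 10% was estimated as 10.02% over 17711 simulated genes without change. With the 200 changed genes included it came out at 16.2% over 17686 genes, since an intercept-only design counts them as replicate noise, so the estimate from the mice includes their differences. Of 200 simulated lists of 10 genes among 16491 genes, 3% of unchanged lists and 90% of lists moved by 0.3 lay outside the central 95%. Each simulated gene varied independently, so the 3% does not cover lists whose members vary together. The simulation also held no reads shared between genes. The result of 0 unchanged genes called therefore does not cover errors from splitting such reads.

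Gene lists, pairs and the rule for named genes were fixed before the data were examined. The genes named are members of 34 lists (11 cell classes, 9 other tissues, 6 states, 8 families), the 10 most abundant nuclear protein-coding genes, the 5 most abundant long non-coding RNAs, the 10 genes highest in each mouse relative to the other, the 5 genes with the largest difference between tables in each direction, and the major isoforms of 15 genes. Some of these genes are not reported here, though counts and medians include them. Alternatives tried were other TPM thresholds (0.1 and 5), a pseudocount of 0.1, TPM rescaled to nuclear protein-coding genes, members with at least 10 counts, DESeq2 1.42.0 size factors, library totals, spike-in totals, other count minimums (20 and 500), no filter, matching on length, the read-based table and leaving out each mouse. Chosen after seeing the data were a correction for GC content and length, genes past the threshold in both tables, and leaving out genes on which the tables differ by over 0.5.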

Results

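Total RNA was sequenced from the left cerebral cortex of 2 male mice of the F1 hybrid strain B6CASTF1/J, a cross of the B6 laboratory strain with the CAST strain, at an age of 36 days. Each mouse gave 1 library made from 300 ng of RNA, with ERCC spike-in RNAs (a set of synthetic transcripts added to every sample) and reduction of ribosomal RNA, per the labels. The total expected count was 29915463 in replicate 1 and 27988085 in replicate 2. Both libraries belong to 1 group, so the design holds no comparison between conditions. The values below describe the tissue and the difference between its 2 mice. With 2 mice an exact permutation test cannot give a p below 0.5, so no p-value was computed across genes. Intervals on counts cover counting error only.

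The first question was which genes the tissue expressed. Of 22028 protein-coding genes, 12902 (58.6%) reached a TPM (transcripts scaled to a fixed sum per library) of 1 in both mice, and 454 did so in 1 mouse only. The most abundant nuclear protein-coding gene was Snap25, a component of the synaptic vesicle fusion machinery (ENSMUSG00000027273.13, chromosome 2, 136713453 to 136782428 in mm10), at a TPM of 1250.4 ± 38.0 (SD, n = 2). Camk2a, a synaptic kinase of excitatory neurons (ENSMUSG00000024617.16, chromosome 18, 60925618 to 60988152), followed at 1097 ± 7.77, and the chaperone Hspa8 at 1057 ± 104. The other abundant genes encoded glycolytic enzymes (Gapdh at 1047 ± 21.9, Aldoa at 1007 ± 28.5), the cytoskeletal protein Actb (1004 ± 28.7), the calcium sensor Calm2 (978 ± 54.9), and the peptide-processing enzyme Cpe (970.5 ± 24.1). Gapdh, which has many pseudogene copies, stood at 3503 in the read-based table, so its level is uncertain. Snurf was listed at 1042 ± 47.3, but its model of 216 nucleotides lies inside Snrpn. Its read-based value was 0, which can also stand for a missing entry, so its level is uncertain.

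Among long non-coding RNAs, Malat1 (ENSMUSG00000092341.3, chromosome 19, 5795690 to 5802672) stood at a TPM of 5681 ± 1225 and Meg3, an imprinted RNA of chromosome 12, at 1293 ± 356. Gm26917 (11126 ± 740.1) and Gm42418 (2063 ± 4.13), which lie next to each other on chromosome 17, and Rmrp (3203 ± 54.6) completed the 5 most abundant. The origin of the reads on Gm26917 and Gm42418 was not tested, so their levels as long non-coding RNAs are uncertain. Rmrp has a second gene model at the same place, so the level of Rmrp is uncertain too.

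Markers of excitatory neurons were the most abundant of the cell class lists fixed before the data were examined. All 10 members reached a TPM of 1 in both mice, with a median of 109 ± 0.407 (SD, n = 2). On the log2(TPM + 1) scale this level was 6.56, against 7.70 with TPM rescaled to nuclear protein-coding genes and 7.36 in the read-based table, so levels depend on the scale of TPM. They included the vesicular glutamate transporter Slc17a7 at 581 ± 25.1 and the postsynaptic protein Nrgn at 882 ± 88.8. Markers of layers 2 to 4 (8 of 8 members) had a median of 42.0 ± 2.35, layer 5 (8 of 8) of 14.4 ± 1.53 and layer 6 (9 of 9) of 10.4 ± 0.361. Pcp4 of layer 5 (295 and 249.9 in replicates 1 and 2) and Rprm of layer 6 (33.2 ± 5.69) were the most abundant members of those lists. Inhibitory neuron markers (10 of 10) had a median of 39.98 ± 3.08, led by the neuropeptide gene Sst at 180.1 ± 0.750 and the GABA-synthesising enzyme Gad1 at 162 ± 15.9.

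All glial and vascular lists were detected. Oligodendrocyte markers (10 of 10) had a median TPM of 65.2 ± 8.28, with the myelin gene Mbp at 576 and 497 in replicates 1 and 2. Astrocyte markers (10 of 10) had a median of 59.3 ± 2.37, led by the glutamate transporter Slc1a2 at 806 ± 52.5 and by Aldoc at 331 ± 2.48. Microglial markers (10 of 10) had a median of 17.7 ± 0.113, with Csf1r at 33.1 ± 0.820. Endothelial markers (10 of 10) had a median of 13.5 ± 0.679 and mural cell markers (7 of 8) of 5.96 ± 0.247. Oligodendrocyte precursor markers (8 of 8) had a median of 7.07 ± 0.990, with Gpr17 at 18.8 ± 1.63 and Pdgfra at 17.0 ± 2.45.

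Markers of other brain regions and tissues were mostly low. None of the 5 cerebellar markers reached a TPM of 1 in both mice (median 0.045 ± 0.0354), and Barhl1 had 0 counts in both, which allows up to 3 counts. Choroid plexus (2 of 10 members, median 0.540 ± 0.0141), ependymal (2 of 6, 0.720 ± 0.127), olfactory bulb (2 of 5, 0.985 ± 0.276) and hippocampal markers (4 of 7, 1.40 ± 0.368) were near that threshold. Thalamic markers (5 of 6) had a median of 4.10 ± 0.456 and leptomeningeal fibroblast markers (7 of 8) of 5.96 ± 0.520. The striatal list was an exception, with 10 of 10 members detected and a median of 27.5 ± 2.38, including the dopamine signalling protein Ppp1r1b at 134 and 121 in replicates 1 and 2 and the neuropeptide gene Penk at 88.3 and 83.3. Several of its genes, such as Penk and Tac1, are also known in cortical neurons. Whether the piece also held some striatal tissue was not tested. Erythroid markers (5 of 7) had a median of 25.2 ± 4.06, from the globins Hba-a1 (188 ± 3.13) and Hbb-bs (187 ± 1.93), which have near-identical copies and are uncertain. The median of the 11 cell class lists lay above that of the 9 other-tissue lists by 2.97 ± 0.23 on the log2(TPM + 1) scale, or by 1.89 over members with at least 10 counts in both mice.

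**Figure D1:**
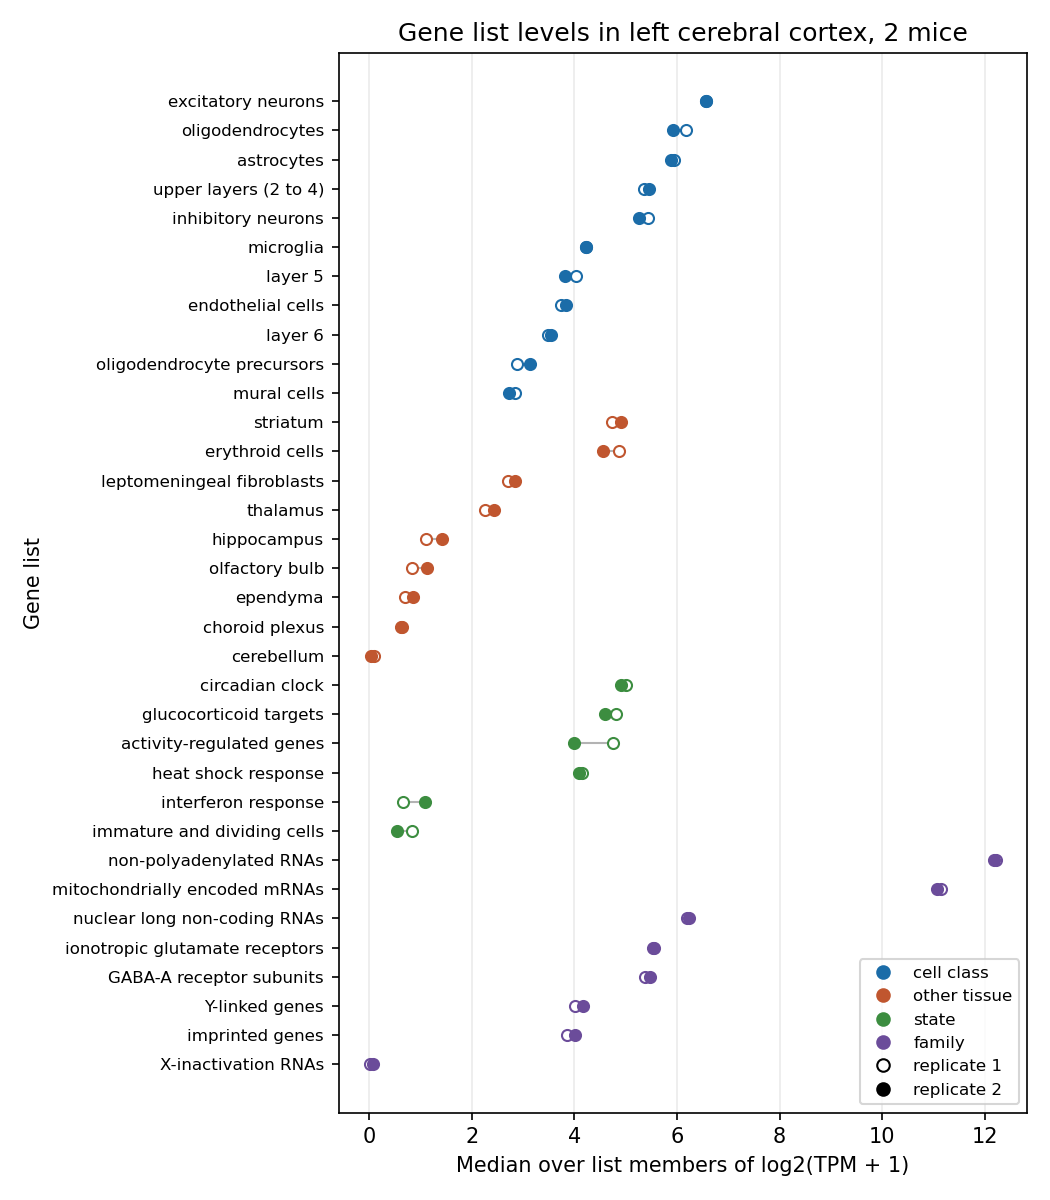
Median of log2(TPM + 1) over the members of each of the 34 gene lists (horizontal axis), with open points for replicate 1 and filled points for replicate 2, coloured by kind of list. Excitatory neuron markers are the highest cell class list (median TPM of 109) and cerebellar markers the lowest list of another region (0.045).

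Lists of receptor families and cell states gave the following levels. All 15 ionotropic glutamate receptor genes were detected in both mice (median TPM 45.3 ± 0.410), with the AMPA receptor subunit Gria2 at 235 ± 19.8 and the NMDA receptor subunit Grin1 at 200.5 ± 10.6. Of 13 GABA-A receptor subunits, 12 were detected (median 41.9 ± 2.09). The undetected member, Gabra6, is a cerebellar gene. Immature and dividing cell markers were low (4 of 9, median 0.620 ± 0.240), although Tubb2b stood at 75.2 ± 2.08 and Dcx at 12.1 ± 3.32, and the division markers Mki67 (0.235 ± 0.0495) and Top2a (0.540 ± 0.354) stayed under 1. Interferon response genes were also low (4 of 10, median 0.858 ± 0.400). Heat shock genes (8 of 8, 18.3 ± 1.32), glucocorticoid targets (8 of 8, 25.5 ± 1.99), clock genes (15 of 15, 31.0 and 28.9 in replicates 1 and 2) and activity-regulated genes (18 of 18, 20.4 ± 7.67) were all detected.

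Of 34 imprinted genes, 28 were detected (median 14.3 ± 1.16), led after Meg3 by Gnas at 754 ± 10.4 and Rian at 604 ± 88.6. H19 had 2 and 4 counts. The 4 Y-linked genes were detected in both males (median 16.7 ± 0.827), and Xist, the RNA that coats an inactive X chromosome, had 5 and 8 counts. The 13 mitochondrially encoded mRNAs had a median of 2196 ± 78.9, and the 8 nuclear long non-coding RNAs of 76.7 ± 5.56. The non-polyadenylated RNAs (7 of 8) had a median of 5073 ± 80.8, on the log2(TPM + 1) scale 12.20, against 0.73 in the read-based table, so their level is uncertain.

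The balance between related genes was measured in 12 pairs fixed before the data were examined, as log2 ratios of TPM + 1. In 11 of the 12 the ratio exceeded, in both mice, the 95th percentile of the difference between the mice at similar abundance. That percentile covers the same gene in 2 mice and not differences in how 2 genes are quantified. Exceeding it therefore shows only a ratio larger than the variation between these mice. Transcripts of the vesicular glutamate transporter Slc17a7 exceeded those of Slc17a6 by 5.38 ± 0.22 (SD, n = 2), a 41.6-fold difference. The potassium chloride exporter Slc12a5 exceeded the importer Slc12a2 by 3.88 ± 0.04 (14.7-fold). Gria2 exceeded Gria1 by 1.23 ± 0.06. The kinase subunit gene Camk2a exceeded Camk2b by 1.96 ± 0.07 and the GABA-synthesising enzyme Gad1 exceeded Gad2 by 1.62 ± 0.01. In the read-based table Gad1 exceeded Gad2 by 1.16, so the SD between the mice understates the uncertainty of this ratio. Among interneuron markers, Sst exceeded Vip by 2.78 ± 0.02, and the ratio of Pvalb to Sst was -2.23 ± 0.31. Slc1a2 exceeded Slc1a3, both astrocyte glutamate transporters, by 2.54 ± 0.14, or by 2.10 in the read-based table. The sodium channel genes Scn8a and Scn2a were close, with a ratio of -0.37 ± 0.02 against a percentile of 0.31. The ratio of the NMDA receptor subunits Grin2a and Grin2b was -0.30 ± 0.12, and in replicate 1 it (-0.21) was smaller than the same percentile. In the read-based table the mean ratio was -0.057.

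Major isoforms were read from the transcript tables for 15 genes with known brain splicing. App was almost entirely App-201 of 695 codons (91.5% ± 0.757 of the gene's TPM, SD, n = 2), and Camk2b mostly Camk2b-209 of 542 codons (89.0% ± 1.78). Snap25-201 held 85.2% ± 1.096, Clta-205 (248 codons) 73.4% ± 0.849, Mapt-204 (372 codons) 68.9% ± 2.26 and Bin1-201 (588 codons) 59.0% ± 1.18. The neurotrophin receptor gene Ntrk2 was split between several isoforms. Ntrk2-201 (38.2% ± 1.53) and Ntrk2-207 (15.3% ± 1.24) both have 821 codons, and Ntrk2-202 has 476 codons (25.2% and 26.8% in replicates 1 and 2). For the myelin gene Mbp, Mbp-211 of 128 codons held 68.0% ± 1.48. Gria2-202 held 59.4% and 49.0% in replicates 1 and 2. The leading isoform of Dlg4 (Dlg4-203) held 58.1% ± 1.85, that of Dnm1 (Dnm1-201) 49.1% ± 0.827 and that of Homer1 (Homer1-207) 32.1% ± 0.509. The read-based table had the same leading isoform for 14 of the 15 genes. The exception was Grin1, with Grin1-201 (39.7% ± 2.38) in the alignment-based table and Grin1-205 in the other, and there Mbp-211 held 32.1% of Mbp and Dlg4-203 held 29.4% of Dlg4.

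Total RNA libraries also hold RNAs without a poly(A) tail, and the shares of RNA classes showed these. Nuclear protein-coding genes took 45.6% ± 0.359 of TPM and 80.3% ± 0.323 of expected counts (SD, n = 2). The class of miscellaneous small RNAs took 32.5% ± 0.701 of TPM but 4.38% ± 0.0960 of counts, mostly from the signal recognition particle RNAs Rn7s1 and Rn7s2 and the transcription regulator RNA Rn7sk (52039 and 56707 TPM). Rn7s1 and Rn7s2, both 300 nucleotides long and on chromosome 12, carried equal counts in each mouse (523601 and 499467), so their reads were shared and their separate levels are uncertain. Mitochondrial ribosomal RNA took 8.00% ± 1.01 of TPM, mitochondrial mRNAs 3.05% ± 0.256 and long intergenic non-coding RNAs 2.79% ± 0.248. The share of long intergenic non-coding RNAs includes Gm26917, at a mean TPM of 11126. The level of Gm26917 is uncertain, so this share is uncertain too.

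The read-based table differed most in these short RNAs. It gave the miscellaneous class 38 and 74 counts, against 1285401 and 1241480 in the alignment-based table, and nuclear protein-coding genes took 74.4% ± 1.33 of its TPM. Across 12902 protein-coding genes the Spearman correlation between both tables was 0.979, where genes are not independent replicates. The major isoform was the same for 75.9% of 11675 genes with at least 2 transcripts. Among protein-coding genes at a TPM of 10 or more, the short mitochondrial genes mt-Atp8 (2049 against 0) and mt-Nd4l (2230 against 23.2), Snurf (1042 against 0), AC149090.1 (218 against 0) and Rpl10-ps3 (145 against 0) were lower in the read-based table. Rpl27 (17.6 against 211), Cycs (18.8 against 215), mt-Co2 (185 against 1545), Rpl27a (55.4 against 437) and Pisd (26.2 against 196) were higher there. Ribosomal protein genes, Cycs and mitochondrial genes have near-identical copies elsewhere in the genome, so their levels are uncertain. A read-based value of 0 can also stand for a missing entry. The levels of mt-Atp8, Snurf, AC149090.1 and Rpl10-ps3 are uncertain for this reason too. So is the level of Pisd, because the read-based and alignment-based values differ.

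Spike-in RNAs took 0.407% of expected counts in replicate 1 (95% exact Clopper-Pearson interval 0.404% to 0.409%) and 0.322% in replicate 2 (0.320% to 0.324%). Over the 34 of 96 ERCC RNAs with a mean count of at least 20, the median log2 ratio of replicate 2 over replicate 1 was -0.42 relative to the mice's own genes, with an SD of 0.21 across RNAs.

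The mice's profiles lay close together. Across 15811 genes with a mean TPM of at least 1, Pearson's r of log2(TPM + 1) was 0.983 and Spearman's rho 0.984, and the median absolute difference was 0.14. The common biological coefficient of variation from edgeR was 8.96% over 17529 genes. The chi-square between the libraries was 11.6 per degree of freedom over 18256 genes, so they were counted as separate libraries and not as 1 library deposited 2 times.

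Genes induced by neuronal activity were among those lowest in replicate 2 relative to replicate 1. Arc, a synaptic plasticity gene (ENSMUSG00000022602.14, chromosome 15, 74669083 to 74672570), had 10044 counts in replicate 1 and 1932 in replicate 2, a log2 ratio of -2.34 (counting interval -2.41 to -2.27). The transcription factor genes Fos (-1.63, interval -1.82 to -1.44), Egr2 (-1.52, -1.81 to -1.25) and Nr4a1 (-1.36, -1.46 to -1.26) were also lower in replicate 2. So were the matricellular gene Ccn1 (-2.19), the transcription factor gene Cebpd (-1.57), the troponin gene Tnnc1 (-1.54), the small GTPase gene Arl4d (-1.44), the phosphatase gene Dusp5 (-1.44) and Tnfrsf25 (-1.35).

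Other genes were higher in replicate 2. Abi3bp, an extracellular matrix gene (ENSMUSG00000035258.15, chromosome 16, 56477878 to 56690135), had 370 and 811 counts, a log2 ratio of 1.17 (counting interval 0.99 to 1.35). It and Ndst4, a heparan sulfate enzyme gene (338 and 693 counts, 1.07), exceeded 1 in both tables. Hist1h2ai (1.12 and 0.72 in the alignment-based and read-based tables), Gm28539 (1.11 and 0.55) and Gemin4 (1.09 and 0.86) exceeded it in the first only. Adam33 (0.98), Sox18 (0.93) and Lrch4 (0.89) completed the 10 highest. The largest ratios, for a second gene model of Nnt (5.79) and of Myl12b (2.72), each share their symbol with an overlapping model. Summed over both models, the ratios were 0.04 for Nnt and -0.11 for Myl12b, so those of the separate models are uncertain. So are the ratios of the mitochondrial genes mt-Co2 (-1.24 in the alignment-based and -0.30 in the read-based table) and mt-Co3 (-1.13 and -0.04).

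Of 11728 protein-coding genes with a mean count of at least 100, 29 differed by over 1 on the log2 scale, 22 lower and 7 higher in replicate 2. Of these 29, 22 also did so in the read-based table, 20 lower and 2 higher, a count chosen after seeing the data. At a mean count of at least 20 the direction of the split turned, with 54 lower and 62 higher among 116 genes. Scaling to spike-in totals moved the median gene up by 0.40 in replicate 2 and gave 67 genes, 8 lower and 59 higher. This comparison has 1 library per mouse and no replicate check.

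**Figure D2:**
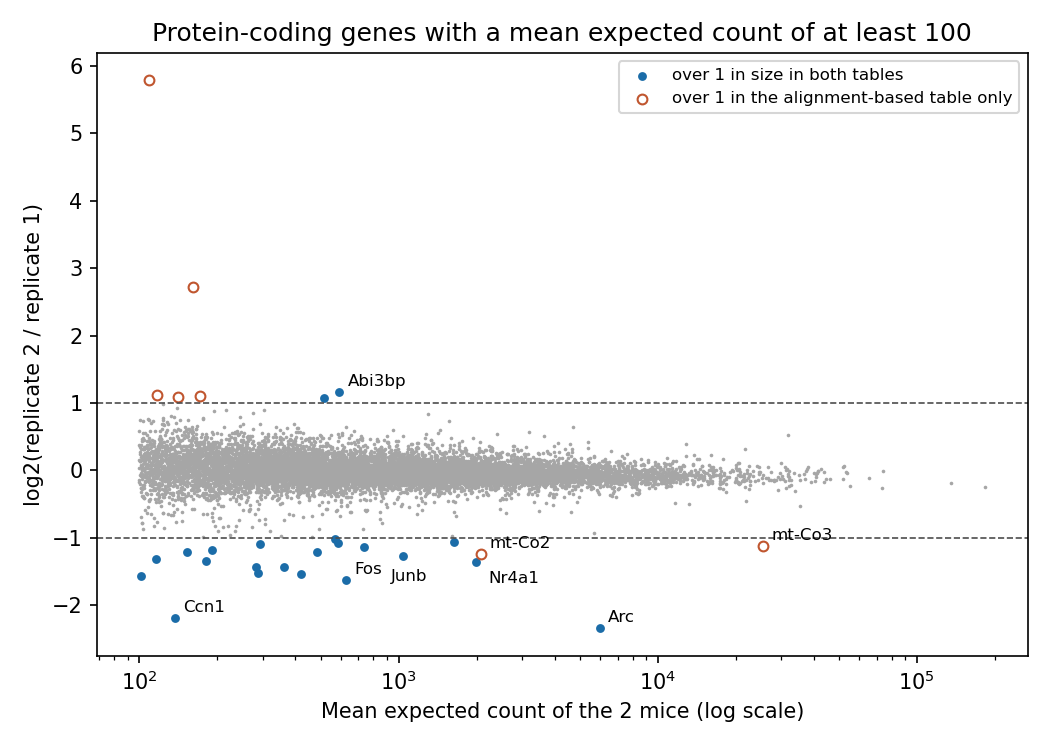
Log2 ratio of replicate 2 over replicate 1 (vertical axis) against the mean expected count (horizontal axis, log scale) for 11728 protein-coding genes. Filled points mark the 22 genes past 1 in size, in the same direction, in both tables, open points the 7 past it only in the alignment-based table, Arc is the lowest point at -2.34, and spike-in scaling would raise every point by 0.40.

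The gene lists were compared between the mice through the median ratio of their members. All 18 activity-regulated genes were lower in replicate 2 (16 of 18 with spike-in scaling), 7 of them by over 2-fold, with a median log2 ratio of -0.76 (1.70-fold), below all 10000 random lists of matched expression. With spike-in scaling the median was -0.37 (1.29-fold), and 3 members were lower by over 2-fold. With TMM scaling the 7 members past 2-fold were Arc, Fos, Egr2, Nr4a1, Ier2 (-1.31), Junb (-1.28) and Dusp1 (-1.07), while Egr1 was at -0.94 and Bdnf at -0.06. Of 8 glucocorticoid targets 7 were lower, with a median of -0.40, or 0.00047 with spike-in scaling, led by Sgk1 (-0.97) and Tsc22d3 (-0.64), while Fkbp5 was at -0.0016. Heat shock genes were lower in 5 of 8 (median -0.17, mean -0.06), or in 0 of 8 with spike-in scaling (median 0.23).

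Oligodendrocyte markers were lower in replicate 2 in 10 of 10 members, with a median of -0.34, or 0.06 with spike-in scaling, including the myelin genes Mog (-0.44) and Mbp (-0.32). Striatal markers were lower in 9 of 10, with a median of -0.29, or 0.11 with spike-in scaling, including the dopamine receptor gene Drd2 (-0.65). Unlike these ratios, the median TPM of the striatal list was 25.8 in replicate 1 and 29.2 in replicate 2, and that of layer 6 was 10.1 and 10.7. Layer 5 markers were lower in 8 of 8 (median -0.24, or 0.16 with spike-in scaling) and layer 6 markers in 7 of 9 (-0.20, or 0.20). Markers of excitatory neurons (-0.09), layers 2 to 4 (0.01), inhibitory neurons (-0.03), astrocytes (-0.10), oligodendrocyte precursors (-0.04), microglia (-0.01), endothelial cells (0.03) and mural cells (0.14) lay within the central 95% of random lists.

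Nuclear long non-coding RNAs were higher in replicate 2 in 7 of 8 members, with a median of 0.47 (1.39-fold) above all 10000 random lists, or in 8 of 8 with a median of 0.87 with spike-in scaling. Malat1 was at 0.40, Meg3 at 0.53, Snhg11 at 0.53 and Neat1, the scaffold of nuclear paraspeckles, at 0.88, while Pantr1 was at -0.33. Over 5286 protein-coding genes, retained-intron transcripts were higher in replicate 2 relative to coding transcripts of the same genes by a median of 0.38 (bootstrap interval over genes 0.37 to 0.39). Clock genes split into 8 higher and 7 lower (median 0.09), or 13 higher and 2 lower with spike-in scaling, while their median TPM was lower in replicate 2. Dbp (0.83), Per3 (0.38), Nr1d1 (0.31) and Nr1d2 (0.28) were higher, and Arntl (-0.50), Per1 (-0.46), Clock (-0.25) and Npas2 (-0.19) were lower. Imprinted genes (18 of 30 higher, median 0.06), leptomeningeal fibroblast markers (5 of 8, 0.25) and Y-linked genes (3 of 4, 0.15) also lay above the central 95%, of which the imprinted list shares Meg3 with the nuclear RNAs. With spike-in scaling these were higher in 30 of 30 (median 0.46), 8 of 8 (0.65) and 4 of 4 (0.55). After correction for GC content and length, an alternative chosen after seeing the data, the Y-linked median was -0.06 and the fibroblast median of 0.15 fell inside the central 95%. With the same correction the mitochondrial mRNAs were lower in 13 of 13, with a median of -0.38 outside it. In the read-based table erythroid markers (-0.21) lay below it and ionotropic glutamate receptors (-0.0025) above it.

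In all, 12 of 31 lists with at least 3 members at a mean count of 20 lay outside the central 95% of random lists, 7 below and 5 above. Lists of unrelated genes would give 1.55. Members of a cell class or state list can vary together between any 2 animals, and some lists share members. The value of 1.55 is therefore not the expected count for such lists. The remaining medians were -0.0034 for ionotropic glutamate receptors, -0.08 for GABA-A receptor subunits, -0.11 for mitochondrial mRNAs, -0.03 for non-polyadenylated RNAs, 0.02 for immature and dividing cells and 0.17 for interferon response genes. For markers of other regions they were 0.13 for choroid plexus, -0.13 for erythroid cells, -0.0073 for hippocampus, 0.08 for thalamus and 0.45 for the olfactory bulb. Lists of ependyma, cerebellum and X-inactivation RNAs had too few members to compare.

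**Figure D3:**
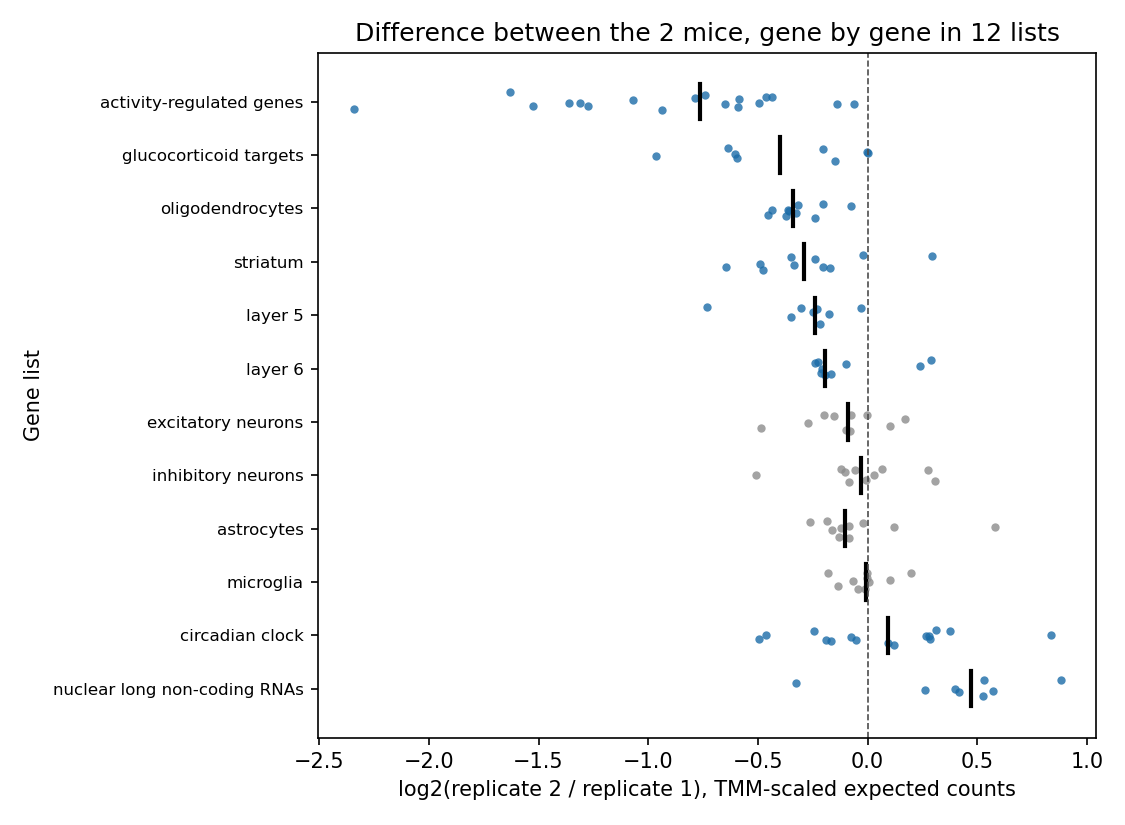
Log2 ratio of replicate 2 over replicate 1 of TMM-scaled expected counts (horizontal axis) for each compared member of 12 gene lists, with black bars at the list medians and blue points for lists outside the central 95% of random lists. All 18 activity-regulated genes lie below 0 (16 with spike-in scaling), and spike-in scaling would raise every point by 0.40, which turns the medians of the oligodendrocyte, striatal, layer 5, layer 6 and glucocorticoid lists above 0.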

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

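No test in this part was chosen after the result was seen. The 26248 tRNA rows of the gene tables enter no comparison of the report. Summed over all these rows, they held 4 expected counts in replicate 1 and 3 in replicate 2. The value of 4 was flagged as above the 3 counts that a count of 0 allows. That limit applies to a single count of 0 and is no detection threshold for such a sum, so no tRNA signal follows. No explanation was tested for this value.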

How the results depend on the processing

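The correction for GC content and length, the count of genes past the threshold in both tables, and leaving out genes on which the tables differ were chosen after seeing the data. The gap between cell class and other-tissue lists was 3.30 with TPM rescaled to nuclear protein-coding genes, 3.59 with a pseudocount of 0.1 and 1.89 over members with at least 10 counts, always with cell classes higher. The coefficient of variation was 8.97% with DESeq2 size factors, 9.45% without a filter and 10.6% in the read-based table. The count of differing genes was 67 with spike-in totals (59 higher, 8 lower, 15 shared with the main 29), 116 at a mean count of at least 20 (62 higher, 54 lower) and 12 at 500 (2 higher, 10 lower). Spike-in totals turned the list medians of layer 5 (0.16), layer 6 (0.20), oligodendrocytes (0.057), striatum (0.11), heat shock (0.23) and glucocorticoid targets (0.00047) to the other side of 0, which follows from a shift of all genes by 0.40. Corrected for GC content and length, 11 lists lay outside, 10 of them among the 12, the fibroblast median was 0.15 and the Y-linked median turned to -0.058; the cause was not tested. The nuclear protein-coding share was 80.3% of counts and 74.4% of read-based TPM, and the spike-in share 0.258% in the read-based table. The share of genes with the same major isoform in both tables ranged from 74.1% to 74.9% with 1 mouse left out. Of the other results on these main values 91 were the same, and of those on single lists, pairs and classes 273 were the same, 107 moved and 4 passed a threshold that they had not passed. Library and spike-in totals move every gene alike, so the unchanged list percentiles under them are fixed by construction and say nothing about stability. With 2 mice, a list level or class share from 1 mouse always lies within the SD around their mean. Such results with a mouse left out were therefore the same by construction, and they add to the counts above without showing stability. With 1 library per mouse, leaving out a mouse gives no value for a difference between mice. No paired analysis was possible because both libraries belong to 1 group. A lower count minimum can only add genes, and all 29 main genes were among the 116. Why the direction of the split turned at that minimum was not tested.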

Other observations

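The correction for GC content and length, the tests of neuron content, of spike-in length and of other copies within a class, and the use of the read-based table (listed as a check before the data were examined) to test read assignment were chosen after the result was seen, as was the choice of Homer1 transcripts. Homer1, a scaffold of excitatory synapses and a member of the activity-regulated list, has short transcripts known to be induced by activity and long ones that are not. The short Homer1-204 of 186 codons had 7068 expected counts in replicate 1 and 4334 in replicate 2, and Homer1-207 of 193 codons had 3294 and 2262. The long Homer1-203 of 366 codons had 2238 and 1954.5, and Homer1-202 of 370 codons had 2394 and 1925. The difference between these transcripts was not tested, with 1 library per mouse.

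The lower level of activity-regulated genes in replicate 2 (list median -0.76) was set against 3 technical explanations. After removing the trend on GC content and length the median was -0.75, which argues against that bias as the whole cause. Markers of excitatory neurons had a median of -0.089, layer 5 markers of -0.24 and layer 6 markers of -0.20, which argues against fewer neurons in the piece as the whole cause. Oligodendrocyte (-0.34) and striatal markers (-0.29) were lower too, while the remaining cell class lists lay within the central 95% of random lists. A smaller part from deep layers or from the make-up of the piece stays open. The read-based table gave -0.81, which argues against the assignment of reads. A difference between the animals or in their handling before dissection may remain, as a hypothesis, and the labels give no handling times. Whether the higher level of retained-intron transcripts in replicate 2 bears on these genes was not tested. No biological explanation was tested, since both mice belong to 1 group.

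The higher level of nuclear long non-coding RNAs in replicate 2 (list median 0.47) was 0.49 after removing the trend on GC content and length, which argues against that bias. Retained-intron transcripts were also higher relative to coding transcripts of the same genes, by a median of 0.38 over 5286 genes, with 79.7% of these genes higher in replicate 2. The read-based table gave the same value of 0.38. A larger share of nuclear or unspliced RNA in replicate 2 is therefore a candidate explanation, which could come from the dissection, the extraction or the animals. No biological explanation was tested, since both mice belong to 1 group.

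Short RNAs such as Rn7s1, Rn7s2 and Rn7sk were nearly absent from the read-based table. Reads given to other copies within the class of miscellaneous small RNAs are argued against, since the whole class held 0.0044% of its alignment-based counts there, while a transfer to other classes stays open (nuclear protein-coding genes of replicate 1 had 23854850 counts in the alignment-based and 25445498 in the read-based table). Over 34 spike-in RNAs the ratio of read-based to alignment-based counts rose with length (Spearman's rho 0.83 and Pearson's r 0.747, each with a two-sided permutation p of 2.0e-05, the smallest that the permutations drawn can give), with rho 0.662 over the 27 of at least 600 nucleotides. Too little room for a fragment on a short RNA is therefore a candidate explanation, although the spike-ins span 505 to 1994 nucleotides and Rn7sk has 331, so it rests on extrapolation. No biological explanation was tested, since both tables come from the same libraries.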
